A study of Arabidopsis thaliana with 99 samples.

How the data were processed

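Messenger RNA of Arabidopsis thaliana leaves was measured on 99 Affymetrix arrays, 3 in each of 33 groups, in the lines Laer, penta and gai. Per the labels, the deposited values are log2 probe set signals. The submitters' processing notes name RMA, whose version is not given in the sources used here. The table held 22810 probe sets, of which the 64 control probe sets of the array maker were left out and 22746 were tested. No column belonged to another sample. Arrays had medians of 5.65 to 6.05 and upper quartiles of 7.84 to 8.04 in 66 arrays of 22 groups. The 33 arrays of the 11 pretreatment and paclobutrazol groups had medians of 6.31 to 6.67 and upper quartiles of 8.75 to 8.89. Whether these sets were normalised apart is not given in the sources used here, so comparisons across them carry that difference. Per the protocol, leaf discs had 100 nM flg22, Alternaria was left for 3 days, Pst DC3000 for 12 h, and 10 µM MeJA was sprayed 1 h before sampling. The duration of pretreatment and the GA dose were not given in the sources used here. Water pretreatment served as the baseline of the pretreated groups, and no mock group accompanied Alternaria, Pst DC3000 or MeJA. The protocol has these 3 applied to plants, while all labels say leaf discs.

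Gene names came from the array annotation and loci from the TAIR10.1 reference. Of the tested probe sets, 13513 carried 1 gene name, 503 carried several and 8730 none, and 13436 of those with 1 name matched a reference locus. In all 13350 genes were named, 152 of them by several probe sets, and such a gene was given by its brightest probe set. Group means were fitted to all arrays with limma 3.58.1 in R 4.3.3, with 66 residual degrees of freedom and 2.63 prior degrees of freedom, and comparisons were taken as contrasts with moderated standard errors. p-values are two-sided and were adjusted over the 22746 probe sets by the Benjamini-Hochberg method in each comparison, with calls at an adjusted p under 0.05. The values were read with the package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. flg22 responses of penta, gai and the pretreated groups were the mean of 1 h and 2 h minus control or 0 h. A difference between lines or pretreatments was the contrast of 2 such responses. The p-values measure only the spread between arrays labelled biological replicates, and 3 arrays per group limit the precision. No 2 arrays were identical, and the highest correlation between arrays was 0.9967.

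The comparisons, their alternatives, 16 gene lists and the rule for naming genes were chosen before the data were examined. The rule named the 5 largest rises and 5 largest falls among called genes with 1 gene name, in comparisons of 2 groups only genes whose arrays did not overlap between the groups. It added up to 4 called members of each list with the largest change and a panel of 13 genes, of which 1, PDF1.2, had a name on the array. The text prints those needed to describe a comparison, not always in order of size. GID1B, CML37 and other genes are also given where a comparison did not call them, chosen after their values were seen in other comparisons. Of 218 members of the fixed lists 27 were named, 12.4 percent, and a list test needed 80 percent, so none was tested as a list. Counts adjusted over the list alone took these 27 together. Another 22 lists were drawn from the named genes by gene family or function after the annotation and the structure of the samples had been seen. They were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 880 tests. Paclobutrazol against water and the flg22 responses after GA or GA+JA against that after JA were added after the sets of arrays had been seen.

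Replicate numbers were checked for pairing by the correlation of same-numbered arrays' deviations from their group means, with every pair above 0.1 needed. This held in 7 of 40 comparisons: flg22 at 1 h (lowest 0.25), flg22(Agrobacterium) at 1 h (0.22), flg22+GA against flg22 (0.22), control penta (0.27), flg22 in gai (0.31), JA against water pretreatment (0.77) and flg22 after GA (0.24). The labels do not say what the numbers share. The procedure was tested on simulated data with 200 changed probe sets, 50 at each fold. For flg22 at 1 h it called 158, 11 of them unchanged, and recovered 19 at 1.5-fold, 33 at 2-fold, 45 at 4-fold and 50 at 8-fold. For the difference of gai from Laer it called 141, 8 of them unchanged, and recovered 11, 29, 43 and 50 at those folds. With no probe set changed it called 0 for control penta by limma. Alternatives were a replicate block, only the groups of the comparison with and without that block, the lowest 30 percent of probe sets left out, quantile normalization over all arrays, equal medians of all arrays, array weights, 1 h or 2 h alone, flg22(Agrobacterium) as the baseline of GA, each array left out in turn, and an estimated correlation for list tests. Leaving out water replicate 3 and JA pretreated 0 h replicate 3 together was added later. A count was taken as moved when it changed more than 1.5 times. Other splits of the same arrays were counted in each comparison, at most 100.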

Results

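Messenger RNA was measured on 99 Affymetrix arrays of Arabidopsis thaliana leaves, in 33 groups of 3 arrays labelled as biological replicates. The plants belonged to 3 lines labelled Laer, penta and gai. The labels do not spell these names out. gai is also the name of a gene for a DELLA protein, one of the repressors of growth that gibberellin (GA) removes. Laer leaf discs were sampled as control or 1 h and 2 h after flg22, a peptide of bacterial flagellin that the immune receptor FLS2 recognises, after flg22(Agrobacterium), after GA, or after flg22 with GA. Control, flg22 1 h and flg22 2 h groups existed in penta and in gai as well. Laer and penta plants were also inoculated with the fungus Alternaria brassicicola and sampled 3 days later, or infiltrated with the bacterium Pseudomonas syringae Pst DC3000 and sampled after 12 h. Plants of the 3 lines were sprayed with methyl jasmonate (MeJA), a defence hormone, and sampled after 1 h. Laer groups pretreated with jasmonate (JA), GA or both were sampled 0 h, 1 h and 2 h after flg22. A water pretreated group and a group given paclobutrazol, an inhibitor of GA synthesis, completed the set. Array medians lay between 5.65 and 6.05 on the log2 scale in 66 arrays and between 6.31 and 6.67 in the 33 arrays of the pretreatment and paclobutrazol groups. Changes are differences of mean log2 values ± SE over 22746 probe sets, with n = 3 arrays per group, and adjusted p-values come from limma. In comparisons of 2 groups, the genes named for the largest changes had no overlap between the arrays of the groups.

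The flg22 groups asked which transcripts the peptide changed within 2 h. At 1 h, the calmodulin-like gene CML37 (AT5G42380, 5.63 ± 0.77, adjusted p = 6.6e-08) rose from 4.9 ± 1.9 to 10.53 ± 0.53 (SD). The peroxidase-family gene AT1G14550 (5.99 ± 1.1), AT1G26380 (5.86 ± 0.86) and AT3G02840 (5.69 ± 0.75) and the acylhydrolase gene DLAH (AT1G30370, 5.67 ± 0.85) rose by similar amounts. AT3G15720 (-3.15 ± 0.49), AT3G52070 (-2.88 ± 0.55) and AT2G45340 (-2.86 ± 0.49) fell most. Of 18 named components of pattern-triggered immunity, 14 rose and 0 fell, among them CML42 (AT4G20780, 3.59 ± 0.62) and CML38 (AT1G76650, 3.02 ± 0.67) and the protease gene SBT3.3 (AT1G32960, 2.52 ± 0.4) (adjusted p = 1.3e-08 with a preset correlation and adjusted p = 0.26 with an estimated correlation). The GA receptor genes moved apart: GID1A (AT3G05120, -2.12 ± 0.39) and GID1C (AT5G27320, -1.18 ± 0.26) fell while GID1B (AT3G63010, 2.06 ± 0.32, adjusted p = 9.3e-07) rose, and SLY1 (AT4G24210, -1.34 ± 0.23), whose F-box protein marks DELLA proteins for removal, fell. Glycosyltransferase genes UGT73D1 (AT3G53150, 4.78 ± 0.59), UGT73B5 (AT2G15480, 3.95 ± 0.48) and UGT73B4 (AT2G15490, 3.08 ± 0.4) rose. At 2 h, AT1G14550 (6.43 ± 1.1), AT1G26380 (5.57 ± 0.86) and CCOAMT (AT1G67980, 5.09 ± 0.78), a caffeoyl-CoA methyltransferase gene, rose most. AT5G48490 (-3.52 ± 0.92), AT1G29660 (-3.46 ± 0.82) and AT2G34620 (-3.45 ± 0.64) fell most. CML37 was still higher (3.26 ± 0.77), and 12 immunity components rose while 1 fell (adjusted p = 0.00039 preset, adjusted p = 0.62 with an estimated correlation).

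Of 28 nuclear photosynthesis genes, 7 fell 1 h after flg22 (adjusted p = 0.0048 with a preset correlation and adjusted p = 0.81 with an estimated correlation). At 2 h 24 fell and 1 rose (adjusted p = 2e-08 preset, adjusted p = 0.62 with an estimated correlation). CaS (AT5G23060, -2.55 ± 0.64), LHCB4.2 (AT3G08940, -2.1 ± 0.65), CHLM (AT4G25080, -2.02 ± 0.48) and PSB27 (AT1G03600, -1.98 ± 0.42), for a thylakoid calcium sensor, an antenna protein, a chlorophyll synthesis enzyme and a photosystem II protein, fell most among them at 2 h. The heat shock genes Hsp70-2 (AT5G02490, 2.86 ± 0.43), Hop3 (AT4G12400, 2.47 ± 0.83) and Fes1A (AT3G09350, 2.41 ± 0.62) rose at 2 h. Among salicylate genes, WRKY53 (AT4G23810, 1.68 ± 0.56), GRX480 (AT1G28480, 1.57 ± 0.49) and SAG101 (AT5G14930, 1.08 ± 0.31) rose at 1 h and UGT76B1 (AT3G11340, 1.91 ± 0.59) at 2 h, and the jasmonate regulator gene MYC4 (AT4G17880, -1.5 ± 0.55) fell at 1 h. At 1 h, 2761 probe sets rose and 3587 fell, 1537 and 1310 of them by at least 2-fold. At 2 h, 3508 probe sets rose and 3986 fell, 1593 and 2127 by at least 2-fold. Of 27 named members of the fixed lists, 9 rose and 6 fell (11 and 8 adjusted over the list alone) at 1 h, and 9 rose and 6 fell (10 and 8 adjusted over the list alone) at 2 h. The count at 1 h was 3915 without Laer flg22 1 h replicate 2, and that at 2 h was 3430 without Laer flg22 2 h replicate 2 and 1242 when the 2 groups were fitted alone (4286 with a replicate block). Leaving out 1 array ended the call of WRKY53 (adjusted p up to 0.21 without Laer control replicate 1 or 3, or Laer flg22 1 h replicate 2) and GRX480 (adjusted p = 0.082 without Laer control replicate 1) at 1 h. MYC4 (adjusted p up to 0.26 without Laer control replicate 1 or 3, or Laer flg22 1 h replicate 2 or 3) and SAG101 (adjusted p up to 0.083 without Laer control replicate 3, or Laer flg22 1 h replicate 2) lost it too. Hop3 (adjusted p up to 0.31 without Laer control replicate 1, or Laer flg22 2 h replicate 2) and UGT76B1 (adjusted p = 0.066 without Laer flg22 2 h replicate 1) lost the call at 2 h. CaS (adjusted p = 0.052), LHCB4.2 (adjusted p = 0.25) and Fes1A (adjusted p = 0.054) lost it too without Laer flg22 2 h replicate 2.

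flg22(Agrobacterium) carries the name of a bacterium whose flagellin peptide is known to escape FLS2. No probe set was called by limma against control at 1 h or at 2 h, and 472 and 608 had an unadjusted p under 0.05. PDF1.2 (AT5G44420, -0.16 ± 0.74 at 1 h and 0.94 ± 0.74 at 2 h), a defensin gene of jasmonate and ethylene defence, and GID1B (0.32 ± 0.32 and 0.03 ± 0.32) were not called. The 1 h count was 2 without Laer control replicate 1 and 1 without Laer flg22(Agrobacterium) 1 h replicate 3, and the 2 h count was 1 without Laer flg22(Agrobacterium) 2 h replicate 2.

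Set directly against flg22(Agrobacterium), flg22 raised AT3G12910 (6.58 ± 0.74), CML37 (6.09 ± 0.77) and AT4G18540 (5.99 ± 0.71) at 1 h and lowered AT3G15720 (-3.66 ± 0.49), AT2G28720 (-2.98 ± 0.41) and AT5G42760 (-2.84 ± 0.63). At 2 h, AT1G26380 (5.54 ± 0.86), AT4G37290 (5.15 ± 0.87) and AT4G22640 (4.5 ± 0.58) were higher, and AT3G15720 (-3.68 ± 0.49), AT4G30660 (-3.17 ± 0.62) and PDF1.2 (-2.29 ± 0.74, adjusted p = 0.012) were lower. Immunity components rose in 15 of 18 cases at 1 h (adjusted p = 8.7e-10 preset, adjusted p = 0.21 with an estimated correlation), with the ubiquitin ligase gene PUB23 (AT2G35930, 2.87 ± 0.51) among them. Endoplasmic reticulum stress genes rose in 8 of 14 cases at 2 h (adjusted p = 0.0079 preset, adjusted p = 0.65 with an estimated correlation). At 2 h 23 of 28 photosynthesis genes fell, PORB (AT4G27440, -2.52 ± 0.37), for protochlorophyllide oxidoreductase, furthest (adjusted p = 3.6e-08 preset, adjusted p = 0.62 with an estimated correlation). In all, 2587 probe sets rose and 3487 fell at 1 h, and 4072 probe sets rose and 4193 fell at 2 h. The counts were 3887 without Laer flg22 1 h replicate 2 and 4168 without Laer flg22 2 h replicate 2. The 2 h count was 2511 with its groups fitted alone and 0 with a replicate block added. Calls of named genes that ended when 1 array was left out were those of PDF1.2 (adjusted p up to 0.12 without Laer flg22 2 h replicate 2, or Laer flg22(Agrobacterium) 2 h replicate 2).

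GA given to leaf discs asked what the hormone itself changed. The GA receptor gene GID1B fell from 7.93 ± 0.32 to 5.9 ± 0.13 (SD) at 1 h (-2.03 ± 0.32, adjusted p = 0.00024) and by a similar amount at 2 h (-2.4 ± 0.32, adjusted p = 3.9e-06). At 2 h SLY1 (-1.32 ± 0.23) fell too, as did IQD22 (AT4G23060, -1.65 ± 0.36), CSLC04 (AT3G28180, -1.49 ± 0.33) and AT5G01850 (-1.35 ± 0.29), and the expansin gene EXPA9 (AT5G02260, 1.39 ± 0.25, adjusted p = 0.0017), whose product loosens cell walls, rose. As a group, 8 genes of GA receptors and signalling lay lower at 1 h (median -0.79, adjusted p = 1.7e-11 with a preset correlation and adjusted p = 7.2e-07 with an estimated correlation) and at 2 h (median -0.7, adjusted p = 8.7e-10 preset, adjusted p = 5.2e-06 with an estimated correlation). In all, 4 probe sets fell and 0 rose at 1 h by limma, and at 2 h, 3 probe sets rose and 14 fell. At 1 h 504 had an unadjusted p under 0.05, fewer than the share of 0.05 expected with no change. The 2 h count was 9 without Laer control replicate 1 or 3 and 8 without Laer GA 2 h replicate 2 or 3, and 0 by limma with only its groups fitted (0 with a replicate block). The 1 h count was 2 with only its groups and 0 with a replicate block added. Against flg22(Agrobacterium) 2 h in place of control, EXPA9 was 0.62 (adjusted p = 1), CSLC04 -1.08 (adjusted p = 0.83), AT5G01850 -0.87 (adjusted p = 1) and IQD22 -1.63 (adjusted p = 0.071). Without single arrays, limma no longer called IQD22 (adjusted p up to 0.35 without Laer control replicate 1, 2 or 3, or Laer GA 2 h replicate 2 or 3) and CSLC04 (adjusted p up to 0.81 without Laer control replicate 1, 2 or 3, or Laer GA 2 h replicate 2 or 3). AT5G01850 (adjusted p up to 0.34 without Laer control replicate 1, 2 or 3, or Laer GA 2 h replicate 2 or 3) lost it too.

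Adding GA to flg22, tested over 1 h and 2 h on 12 arrays, asked what GA added, its own effect included. GID1B (-1.14 ± 0.23, adjusted p = 0.017) and SLY1 (-0.85 ± 0.16, adjusted p = 0.011) lay lower than with flg22 alone, and the 8 GA genes lay lower as a group (adjusted p = 8.3e-07 preset, adjusted p = 0.00031 with an estimated correlation). CML37 and the other immunity components were not called. By limma 5 probe sets fell and 0 rose, with 872 at an unadjusted p under 0.05. The count was 9 or 3 without Laer flg22 1 h replicate 1 or 3, 3 without Laer flg22 2 h replicate 2, 3 without Laer flg22+GA 1 h replicate 1 or 3 and 3 without Laer flg22+GA 2 h replicate 3, and 0 at either time alone or with only these groups fitted, but 8 with only these groups and a replicate block. The call ended when 1 array was left out for GID1B (adjusted p up to 0.25 without Laer flg22 1 h replicate 2 or 3, or Laer flg22 2 h replicate 1 or 2, or Laer flg22+GA 1 h replicate 1 or 3, or Laer flg22+GA 2 h replicate 3) and SLY1 (adjusted p up to 0.12 without Laer flg22 1 h replicate 3, or Laer flg22 2 h replicate 3, or Laer flg22+GA 1 h replicate 2).

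Control discs of penta and Laer differed in few genes. In penta, the disease resistance gene CSA1 (AT5G17880, 3.32 ± 0.16, adjusted p = 7.6e-27) and AT1G58025 (5.05 ± 0.2) were higher, and AT5G18340 (-3.08 ± 0.21) and AT3G05730 (-2.79 ± 0.57) and the plantacyanin gene ARPN (AT2G02850, -2.42 ± 0.29) lower. The GA receptor genes GID1B (-1.81 ± 0.32, adjusted p = 0.00024) and GID1A (-1.64 ± 0.39) and SLY1 (-1.01 ± 0.23) were lower, and the 8 GA genes lay lower as a group (adjusted p = 2.5e-07 preset, adjusted p = 0.00019 with an estimated correlation). Of all probe sets, 75 were higher and 188 lower. Of 27 named members of the fixed lists, 3 were lower and 0 higher (6 and 0 adjusted over the list alone). The count was 126 or 87 without Laer control replicate 1 or 3 and 159 or 91 without penta control replicate 1 or 2, 39 with these groups fitted alone (445 with a replicate block), and 761 with array weights. Leaving out 1 array ended the call of GID1A (adjusted p up to 0.14 without Laer control replicate 1 or 3, or penta control replicate 2 or 3) and AT3G05730 (adjusted p = 0.081 without penta control replicate 1). SLY1 (adjusted p = 0.096 without penta control replicate 2) lost it too.

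Control discs of gai differed from those of Laer more widely. Small heat shock protein genes AT1G54050 (5.61 ± 0.86), AT2G29500 (5.49 ± 1.2) and AT1G53540 (5.17 ± 1.1) were higher in gai, as were the cochaperone genes Hop3 (4.22 ± 0.83) and Fes1A (3.89 ± 0.62) and 6 of 10 heat shock genes in all (adjusted p = 2.8e-06 preset, adjusted p = 0.16 with an estimated correlation). Glycosyltransferase genes UGT73B4 (4.27 ± 0.4) and UGT73B5 (3.54 ± 0.48), the jasmonate regulator gene MYC3 (AT5G46760, 1.56 ± 0.16, adjusted p = 5.9e-11), CML37 (3.7 ± 0.77) and CML38 (2.98 ± 0.67) were higher. The defensin genes PDF1.2b (AT2G26020, -3.32 ± 0.89) and PDF1.2 (-3.21 ± 0.74, adjusted p = 0.0017) were lower. Photosynthesis genes were lower in 14 of 28 cases, NdhN (AT5G58260, -2.16 ± 0.6) and LHCB4.3 (AT2G40100, -1.9 ± 0.45) among them (adjusted p = 9.9e-09 preset, adjusted p = 0.61 with an estimated correlation). Autophagy genes were higher in 4 of 10 cases, ATG8H (AT3G06420, 1.67 ± 0.35) furthest (adjusted p = 0.0063 preset, adjusted p = 0.65 with an estimated correlation), and so were the cold and dehydration genes HIS1-3 (AT2G18050, 1.94 ± 0.47) and COR27 (AT5G42900, 3.58 ± 0.68). GID1B was not called (0.43 ± 0.32). Of 27 named members of the fixed lists, 3 were higher and 4 lower (7 and 4 adjusted over the list alone). In all, 1749 probe sets were higher and 1666 lower. The count was 1925 or 1669 without Laer control replicate 1 or 3 and 2225 or 1772 without gai control replicate 2 or 3, and 1831 with these groups fitted alone. It was 0 by limma with a replicate block added to that fit. Calls of named genes that ended when 1 array was left out were those of XTH18 (adjusted p up to 0.073 without Laer control replicate 1 or 3) and NdhN (adjusted p up to 0.13 without Laer control replicate 3, or gai control replicate 3).

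The penta and gai groups given flg22 asked whether the flg22 response depended on the line, taken as the mean of 1 h and 2 h against control of the same line. In penta, AT1G14550 (5.32 ± 0.97), the glutamate receptor-like gene GLR2.9 (AT2G29100, 5.12 ± 0.51, adjusted p = 2.5e-11) and AT1G51920 (4.96 ± 0.65) and AT5G37490 (4.71 ± 0.7) rose, and AT3G15720 (-4.1 ± 0.43), AT1G60010 (-3.5 ± 0.52) and AT2G03980 (-3.46 ± 0.5) fell. GID1B rose (2.58 ± 0.28) and PDF1.2 fell (-2.28 ± 0.64). Immunity components rose in 14 of 18 cases (adjusted p = 8e-05 preset, adjusted p = 0.6 with an estimated correlation). In penta 16 of 28 photosynthesis genes fell (adjusted p = 4.4e-06 preset, adjusted p = 0.68 with an estimated correlation), with LHCB4.2 (-1.94 ± 0.56) and PAM68 (AT4G19100, -1.83 ± 0.37) the furthest. UGT73D1 (3.94 ± 0.51) and UGT73B5 (2.52 ± 0.42) rose, and GID1A (-1.21 ± 0.34) and SLY1 (-0.74 ± 0.2) fell. In all, 3895 probe sets rose and 4258 fell. The difference between the penta and Laer responses was called for 5 probe sets by limma, 812 at an unadjusted p under 0.05: AT5G16230 (1.7 ± 0.23, adjusted p = 2.5e-06) changed more upward in penta, and AT1G14930 (-1.36 ± 0.26) and AT5G59990 (-1.23 ± 0.23) more downward. That count was 3 or 12 without Laer control replicate 1 or 2 and 2 without penta control replicate 1. It was 0 with its groups fitted alone (0 with a replicate block) and 1 at 1 h alone. Without single arrays, limma no longer called PDF1.2 (adjusted p = 0.056 without penta control replicate 1) and GID1A (adjusted p = 0.077 without penta control replicate 1) in penta. AT1G14930 (adjusted p up to 0.18 without Laer control replicate 1, or penta control replicate 1, or penta flg22 2 h replicate 3) and AT5G59990 (adjusted p up to 0.41 without Laer control replicate 1, or penta control replicate 1 or 2) lost the call in the difference from Laer.

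In gai, 1 probe set rose and 12 fell after flg22 by limma, 1824 at an unadjusted p under 0.05. AT5G10040 (-1.51 ± 0.26), AT5G66985 (-1.33 ± 0.19) and AT4G33960 (-1.28 ± 0.25) fell. Against Laer, the response of gai was lower for CML37 (-4.63 ± 0.94, adjusted p = 0.0037), AT3G02840 (-4.32 ± 0.92), the xyloglucan endotransglucosylase gene XTH18 (AT4G30280, -4.3 ± 0.89), CCOAMT (-4.05 ± 0.95) and UGT73B4 (-3 ± 0.49). It was higher for AT3G15720 (2.8 ± 0.6) and PORB (1.76 ± 0.45). The difference was positive for 445 probe sets and negative for 871, including 4 of 18 immunity components (adjusted p = 2.1e-06 preset, adjusted p = 0.45 with an estimated correlation). In control discs CML37 (3.7 ± 0.77), XTH18 (2.8 ± 0.73), CCOAMT (4.42 ± 0.78) and UGT73B4 (4.27 ± 0.4) already stood higher in gai than in Laer and AT3G15720 (-3.02 ± 0.49) lower, and that state enters the difference. The difference was called for 1316 probe sets on all arrays, 281 or 251 without Laer control replicate 1 or 3, 707 without Laer flg22 1 h replicate 2, 854, 504 or 2958 without Laer flg22 2 h replicate 1, 2 or 3, 592 or 477 without gai control replicate 2 or 3 and 846 without gai flg22 2 h replicate 3. As many came from 8 of 100 splits of its 18 arrays, the real one included. With only these arrays fitted it was 7 (818 with a replicate block), and it was 452 at 1 h alone and 652 at 2 h alone. The gai response alone was 23 with a replicate block, 31, 1 or 20 without gai control replicate 1, 2 or 3, 22 without gai flg22 1 h replicate 3 and 8 without gai flg22 2 h replicate 1. That response was 29 with only its groups (705 with a replicate block) and 4 at 2 h alone. Single arrays carried the calls of AT5G10040 (adjusted p up to 0.16 without gai control replicate 2 or 3) and AT5G66985 (adjusted p = 0.062 without gai control replicate 2) in gai. AT4G33960 (adjusted p up to 0.42 without gai control replicate 2 or 3, or gai flg22 1 h replicate 1, or gai flg22 2 h replicate 1) lost it too. PORB (adjusted p up to 0.094 without Laer control replicate 1, or gai control replicate 3) and CCOAMT (adjusted p up to 0.068 without Laer control replicate 3, or gai control replicate 3) lost the call in the difference from Laer.

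**Figure D1:**
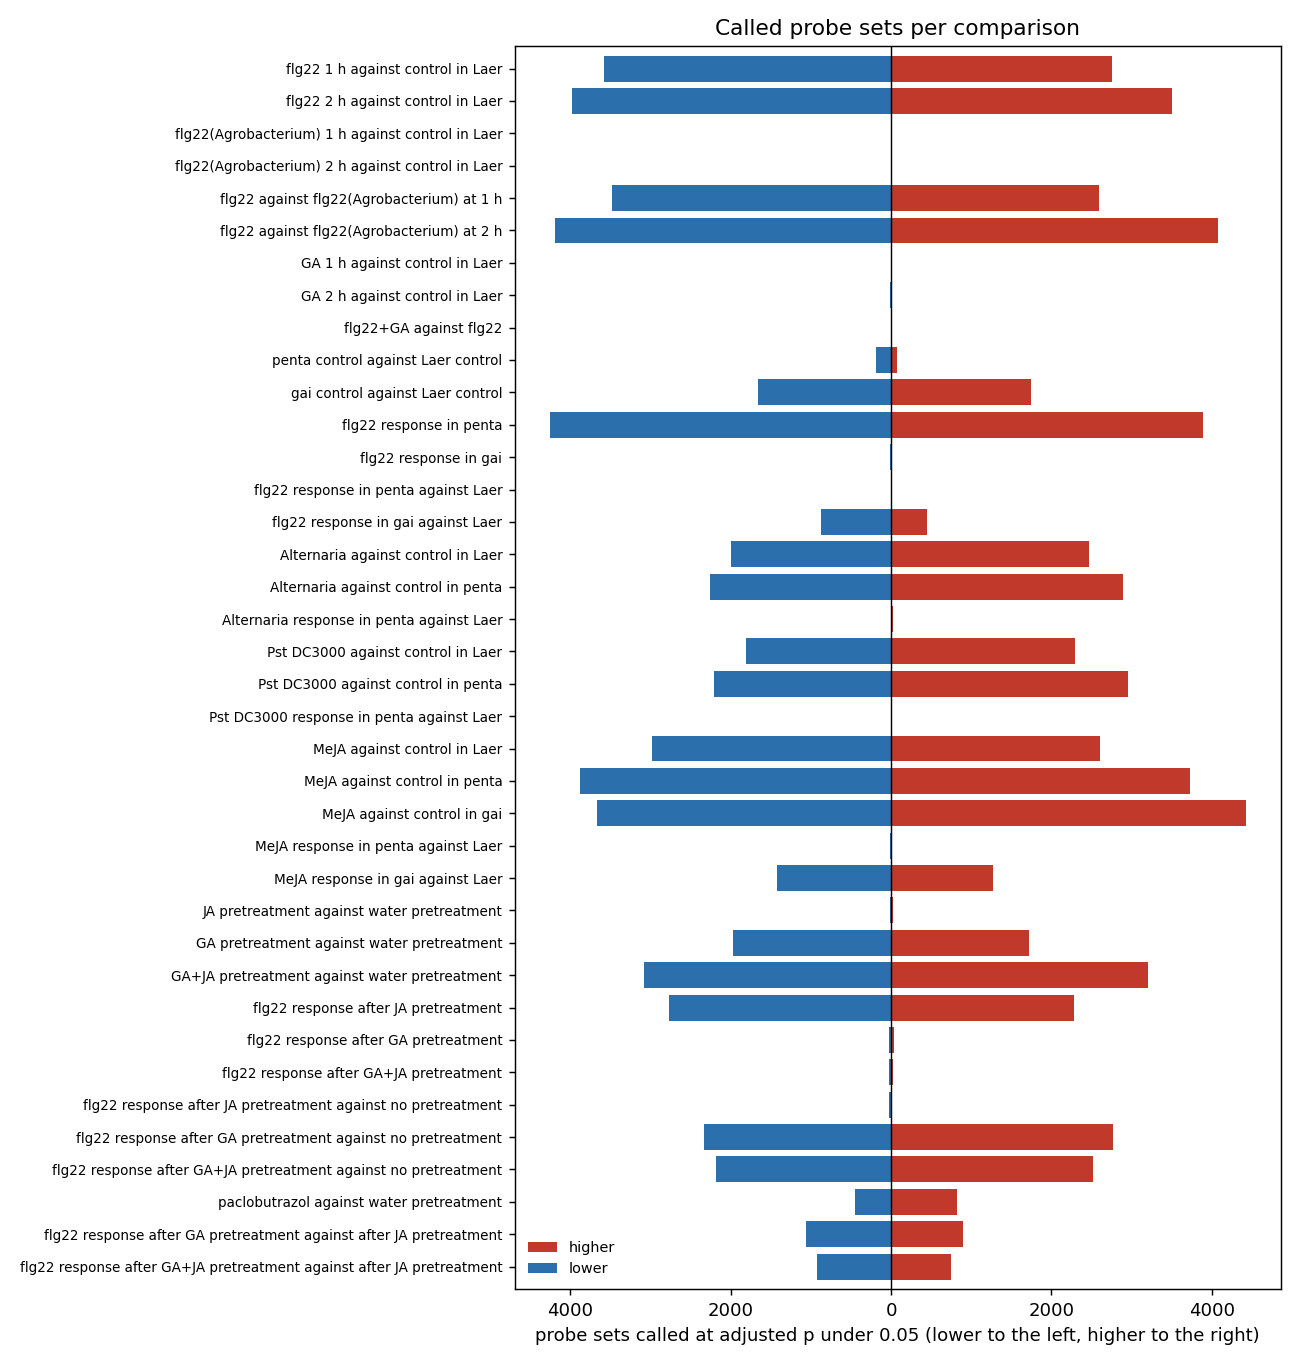
Probe sets called at adjusted p under 0.05 in 38 comparisons, higher to the right and lower to the left of 0. flg22 called 6348 probe sets at 1 h in Laer, from 3 arrays against 3. The mean of 1 h and 2 h against control, from 6 arrays against 3, called 8153 in penta and 13 in gai, the latter 705 with only its groups and a replicate block.

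Plants inoculated with Alternaria showed what 3 days with the fungus changed in Laer and penta. In Laer, AT1G67870 (4.21 ± 0.31, adjusted p = 3.1e-18), the beta-glucosidase gene PYK10 (AT3G09260, 3.7 ± 0.48) and PORB (3.57 ± 0.37) rose, as did PDF1.2 (2.89 ± 0.74, adjusted p = 0.0025). The lipid-transfer-family gene AT4G22470 (-7.56 ± 0.36), AT3G46280 (-7.45 ± 0.34) and AT5G48430 (-6.02 ± 0.38) and the ubiquitin ligase gene PUB22 (AT3G52450, -4.73 ± 0.4) fell. Of 18 immunity components, 1 rose and 10 fell (adjusted p = 1.4e-06 preset, adjusted p = 0.42 with an estimated correlation). GID1B fell (-2.25 ± 0.32). Cold and dehydration genes COR15B (AT2G42530, 3.46 ± 0.63) and OSM34 (AT4G11650, 3.49 ± 0.76), for osmotin, rose, 4 of 12 in all with 1 lower (adjusted p = 0.022 preset, adjusted p = 0.59 with an estimated correlation). Plastid-encoded psaA (-2.21 ± 0.36), of photosystem I, fell. In penta, the auxin conjugation gene GH3.3 (AT2G23170, 5.77 ± 0.62, adjusted p = 2.6e-11) and OSM34 (5.5 ± 0.76) rose, PDF1.2 rose (3.22 ± 0.74), AT4G22470 (-7.31 ± 0.36) and PUB22 (-5.52 ± 0.4) fell, and GID1B was not called (-0.28 ± 0.32). In Laer 2471 probe sets rose and 1992 fell, and in penta 2897 probe sets rose and 2254 fell. Of 27 named members of the fixed lists in Laer, 4 rose and 8 fell (5 and 9 adjusted over the list alone). With only their groups and a replicate block the counts were 1228 in Laer and 2622 in penta. The protocol has Alternaria, Pst DC3000 and MeJA applied to plants, while all labels say leaf discs. No mock group accompanied them. If they were intact plants, changes after each cannot be told apart from a difference between discs and plants. Leaving out 1 array ended the call of PDF1.2 (adjusted p = 0.051 without Laer control replicate 3).

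The Alternaria response differed between penta and Laer for 33 probe sets, 26 more upward and 7 more downward in penta. AT1G62760 (4.24 ± 0.7, adjusted p = 2e-04), ARPN (2.25 ± 0.41) and GID1B (1.96 ± 0.45, adjusted p = 0.037) differed upward, and AT1G16360 (-1.87 ± 0.4) and AT1G14930 (-1.72 ± 0.3) downward. In control discs GID1B (-1.81 ± 0.32) and ARPN (-2.42 ± 0.29) already stood lower in penta than in Laer, and that state enters the difference. The 8 GA genes differed upward as a group (adjusted p = 4.2e-06 preset, adjusted p = 0.00078 with an estimated correlation). With only these 12 arrays fitted the count was 1 (0 with a replicate block), and GID1B was 1.87 (adjusted p = 0.1) with the medians of all arrays made equal. Calls of named genes that ended when 1 array was left out were those of GID1B (adjusted p up to 0.22 without Laer control replicate 1 or 2, or penta control replicate 2 or 3, or Laer Alternaria replicate 1 or 3, or penta Alternaria replicate 2 or 3) and AT1G16360 (adjusted p up to 0.097 without Laer control replicate 1 or 2, or penta control replicate 2 or 3).

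Infiltration with Pst DC3000 asked the same of a bacterium at 12 h. In Laer, AT2G30540 (4.07 ± 0.29, adjusted p = 3.8e-18), the cold-regulated gene COR27 (3.52 ± 0.68), the auxin response gene IAA29 (AT4G32280, 3.24 ± 0.58) and the chitinase gene CHI (AT2G43570, 3.13 ± 0.58) rose. AT3G15650 (-5.7 ± 0.74), AT5G48430 (-5.45 ± 0.38) and AT5G18840 (-5.25 ± 0.52) fell, as did PDF1.2 (-2.99 ± 0.74, adjusted p = 0.002) and the immunity regulator gene WRKY22 (AT4G01250, -3.16 ± 0.43). Of 18 immunity components, 1 rose and 7 fell (adjusted p = 0.022 preset, adjusted p = 0.75 with an estimated correlation). In penta, the expansin gene EXPA8 (AT2G40610, 3.62 ± 0.72, adjusted p = 6.3e-05) and COR15B (3.49 ± 0.63) rose, and AT5G48430 (-6.07 ± 0.38), the peroxidase gene Prx37 (AT4G08770, -5.59 ± 0.73) and PDF1.2 (-3.77 ± 0.74) fell. In Laer 2291 probe sets rose and 1809 fell, and in penta 2952 probe sets rose and 2212 fell. With only its groups fitted the Laer count was 2626, and with a replicate block added to such fits the counts were 371 in Laer and 2956 in penta. The responses differed for 5 probe sets by limma, 922 at an unadjusted p under 0.05. CSA1 (1.13 ± 0.23) differed upward in penta and the triterpene synthase gene LUP5 (AT1G66960, -1.93 ± 0.2, adjusted p = 2.2e-10) downward. CSA1 already stood 3.32 ± 0.16 higher in control penta than in control Laer, and that state enters the difference. That count was 3 without Laer control replicate 1 and 3 or 10 without Laer Pst DC3000 replicate 2 or 3, 1 with only its groups and a replicate block, and 0 once the dimmest 30 percent of probe sets were left out. Without single arrays, limma no longer called CSA1 (adjusted p up to 0.19 without Laer control replicate 1 or 3, or penta control replicate 3, or Laer Pst DC3000 replicate 1 or 2, or penta Pst DC3000 replicate 2 or 3).

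MeJA at 1 h had no mock, so the limit given for Alternaria holds too. In Laer, AT4G27654 (6.76 ± 0.44, adjusted p = 4.3e-21), the calmodulin-like gene AT1G76640 (6.74 ± 0.54) and the cold-regulated gene COR15B (6.26 ± 0.63) rose, and the lipid-transfer-family gene AT4G12490 (-7.61 ± 0.33), AT4G22470 (-7.56 ± 0.36) and the peroxidase gene AT5G64120 (-7.03 ± 0.31) fell. The defensin genes PDF1.4 (AT1G19610, -6.9 ± 0.55), PDF1.2b (-5.13 ± 0.89) and PDF1.2 (-2.83 ± 0.74, adjusted p = 0.0024) fell, while OPCL1 (AT1G20510, 2.46 ± 0.37), for a jasmonate synthesis enzyme, rose. PORB rose (3.86 ± 0.37), as did the salicylate pathway genes GRX480 (2.71 ± 0.49) and BSMT1 (AT3G11480, 3.23 ± 0.79), while UGT76B1 fell (-3.05 ± 0.59). Expansins and xyloglucan enzymes rose in 10 of 29 cases and fell in 1 (adjusted p = 0.0042 preset, adjusted p = 0.23 with an estimated correlation). Autophagy genes fell in 9 of 10 cases, ATG8E (AT2G45170, -2.97 ± 0.4) furthest (adjusted p = 1e-05 preset, adjusted p = 0.42 with an estimated correlation), and GA genes in 5 of 8 (adjusted p = 0.011 preset, adjusted p = 0.18 with an estimated correlation). In penta, AT4G27654 (7.31 ± 0.44), AT1G76640 (6.86 ± 0.54) and COR15A (AT2G42540, 5.49 ± 0.73) rose, PDF1.4 fell (-7.31 ± 0.55), and GID1B was not called (0.48 ± 0.32). In Laer 2611 probe sets rose and 2978 fell, and in penta 3733 rose and 3879 fell. Of 27 named members of the fixed lists in Laer, 4 rose and 11 fell (6 and 12 adjusted over the list alone). The responses differed for 18 probe sets, GID1B (2.3 ± 0.45, adjusted p = 0.0067) and ARPN (2.25 ± 0.41) upward and CSA1 (-1.73 ± 0.23) downward in penta. Control penta discs already differed from Laer by -1.81 ± 0.32, -2.42 ± 0.29 and 3.32 ± 0.16 in these genes, and that state enters the difference. That count was 10 without penta MeJA 1 h replicate 1. In Laer the call of BSMT1 ended when 1 array was left out (adjusted p = 0.057 without Laer MeJA 1 h replicate 3). GID1B (adjusted p up to 0.082 without penta control replicate 3, or penta MeJA 1 h replicate 1) lost the call in the difference of penta.

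In gai after MeJA, AT4G34950 (5.09 ± 0.89), AT2G43550 (5.08 ± 0.81), COR15B (4.99 ± 0.63) and PORB (4.69 ± 0.37) rose, with 23 of 28 photosynthesis genes (adjusted p = 1.9e-07 preset, adjusted p = 0.62 with an estimated correlation). CML37 (-5.27 ± 0.77) and the transcription factor gene WRKY53 (-5.01 ± 0.56) fell, with 13 of 18 immunity components while 2 rose (adjusted p = 3e-08 preset, adjusted p = 0.3 with an estimated correlation). The heat shock genes Hop3 (-3.7 ± 0.83) and ATHSP22.0 (AT4G10250, -2.92 ± 0.41) fell, and XERICO (AT2G04240, 1.74 ± 0.25) rose. Before MeJA, control gai discs already stood above Laer in Hop3 by 4.22 ± 0.83 and in 6 of 10 heat shock genes, and below it in 14 of 28 photosynthesis genes. That state enters the changes within gai. PDF1.2 was not called (0.4 ± 0.74). Against Laer, the response was lower in gai for AT1G19020 (-6.24 ± 0.94, adjusted p = 2.2e-06), AT1G76640 (-6.21 ± 0.76), AT4G27654 (-6.21 ± 0.62), CML37 (-6.15 ± 1.1) and the small heat shock gene AT2G29500 (-6.14 ± 1.6). It was higher for PDF1.2b (4.24 ± 1.3), PDF1.2 (3.24 ± 1.1) and XERICO (3.11 ± 0.35), a gene of abscisic acid and GA signalling. Control gai discs were already higher than Laer in AT2G29500 by 5.49 ± 1.2 and in CML37 by 3.7 ± 0.77, and lower in PDF1.2b by -3.32 ± 0.89 and PDF1.2 by -3.21 ± 0.74, so that state enters the difference. In gai 8093 probe sets differed (4423 up), and the response differed from Laer for 2695 (1267 up). The latter count was 1710 without Laer control replicate 3, 1729 without gai control replicate 3, 1659 without Laer MeJA 1 h replicate 1 and 1352 without gai MeJA 1 h replicate 2, and 1298 with its 12 arrays fitted alone (324 with a replicate block). The gai count was 4966 with only its groups and 2716 with a replicate block added. Leaving out 1 array ended the call of PDF1.2 (adjusted p up to 0.11 without Laer control replicate 1 or 2, or gai control replicate 2 or 3, or Laer MeJA 1 h replicate 2 or 3, or gai MeJA 1 h replicate 1 or 2).

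**Figure D2:**
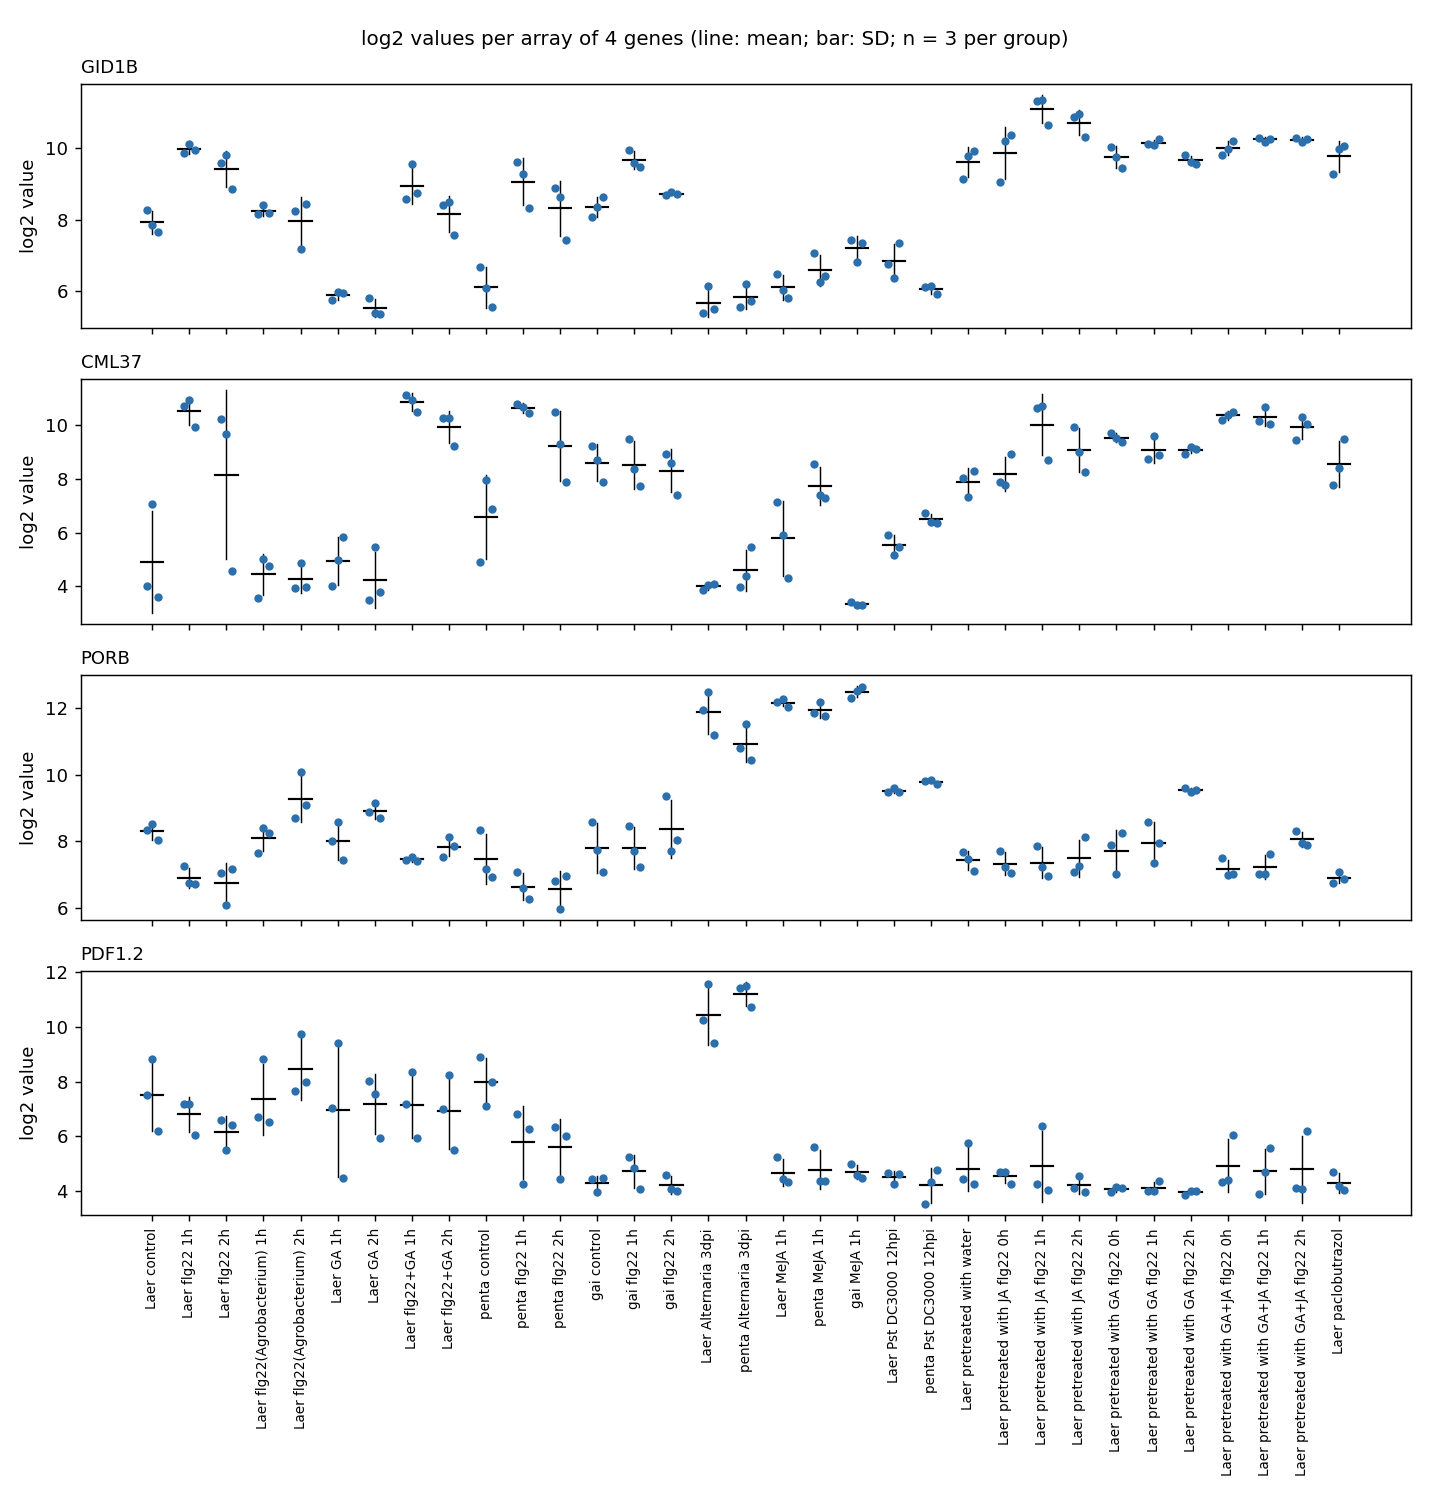
log2 values of GID1B, CML37, PORB and PDF1.2 in each of 99 arrays by group; points are arrays, lines the mean and bars the SD, n = 3 per group. GID1B in Laer was 7.93 ± 0.32 in control and 5.53 ± 0.25 after 2 h of GA.

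Pretreatment with JA, GA or both, before any flg22, was compared with water. After JA, AT5G16980 (2.67 ± 0.5) and OCT5 (AT1G79410, 1.95 ± 0.37) and BSMT1 (3.33 ± 0.79), for a methyltransferase of salicylate and benzoate, were higher, and the nitrate transporter gene NRT2.5 (AT1G12940, -2.72 ± 0.49, adjusted p = 0.0018) was lower. After GA, AT1G14550 (4.79 ± 1.1) and AT3G13610 (4.52 ± 0.71) and AT5G37840 (3.51 ± 0.58) were higher, and AT1G09310 (-4.74 ± 0.75) and AT3G54400 (-3.67 ± 0.72) lower. After GA+JA, AT1G14550 (4.9 ± 1.1) and AT3G56500 (4.21 ± 0.57) and AT3G48450 (4.02 ± 0.6) were higher, and AT1G09310 (-4.64 ± 0.75) lower. Photosynthesis genes were lower in 20 of 28 cases after GA (adjusted p = 6.2e-10 preset, adjusted p = 0.6 with an estimated correlation) and 25 after GA+JA (adjusted p = 1.7e-15 preset, adjusted p = 0.32 with an estimated correlation), NdhL (AT1G70760, -3.43 ± 0.62) and PRK (AT1G32060, -2.99 ± 0.47) among them, with 1 higher in each. GID1A (-1.56 ± 0.39) and SLY2 (AT5G48170, -1.72 ± 0.33) were lower after GA, and GID1B was not called (0.14 ± 0.32). JA called 29 probe sets higher and 8 lower, GA 1723 and 1977, and GA+JA 3207 and 3076. AT1G14550 had an SD of 3.5 among the water arrays, replicate 3 of which stood apart. The JA count was 66 without water replicate 3 and 6 or 143 without JA pretreated 0 h replicate 2 or 3. The GA count was 555, 522 or 6293 without water replicate 1, 2 or 3 and 1777 or 2111 without GA pretreated 0 h replicate 1 or 2. The GA+JA count was 3660 or 3557 without water replicate 1 or 2. With only their groups fitted they were 0, 10 and 1349, and 641, 0 and 604 with a replicate block added. Calls of named genes that ended when 1 array was left out were those of BSMT1 (adjusted p up to 0.83 without water replicate 1, 2 or 3, or JA pretreated 0 h replicate 1 or 2) and AT5G16980 (adjusted p = 0.075 without JA pretreated 0 h replicate 2) after JA. OCT5 (adjusted p = 0.085) and NRT2.5 (adjusted p = 0.083) lost it too without JA pretreated 0 h replicate 2. AT1G14550 (adjusted p up to 0.09 without water replicate 1 or 2) and GID1A (adjusted p up to 0.13 without water replicate 1 or 2) lost the call after GA. SLY2 (adjusted p = 0.052 without water replicate 1) and CML42 (adjusted p up to 0.088 without water replicate 1 or 2) lost it too.

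The flg22 response after pretreatment, the mean of 1 h and 2 h against 0 h, asked whether the hormones altered it. After JA, AT1G14550 (3.9 ± 0.97) and AT1G26410 (3.82 ± 0.6) and AT1G14730 (3.64 ± 0.53) rose, CML42 rose (2.99 ± 0.53) and GID1B rose (1.03 ± 0.28), while AT3G20820 (-3.15 ± 0.63) and AT2G03550 (-3.15 ± 0.67) and LHCB4.2 (-1.85 ± 0.56) fell. In all, 2286 probe sets rose and 2767 fell. After GA, MSRB5 (AT4G04830, 1.88 ± 0.44), AT1G49450 (1.86 ± 0.36) and AT4G30670 (1.63 ± 0.23) rose and AT1G78410 (-3.04 ± 0.72) and AT5G14700 (-2.6 ± 0.61) fell, with 40 probe sets up, 23 down and no immunity component called. After GA+JA, AT2G18480 (1.96 ± 0.2, adjusted p = 3.6e-10) and AT1G49450 (1.73 ± 0.36) rose and AT2G41090 (-2.23 ± 0.54) and AT4G10270 (-1.67 ± 0.25) fell, with 21 up and 27 down. The JA count was 991, 945 or 8248 without JA pretreated 0 h replicate 1, 2 or 3, and 3 with its groups alone (410 with a replicate block), and 2907 at 1 h alone. The GA count was 7 or 11 without GA pretreated 0 h replicate 2 or 3, 28 without GA pretreated flg22 1 h replicate 1 and 31 without GA pretreated flg22 2 h replicate 1. The GA+JA count was 19 or 28 without GA+JA pretreated 0 h replicate 2 or 3 and 31 or 84 without GA+JA pretreated flg22 1 h replicate 1 or 3. They were 2459 and 646 with their groups alone, and 4354 and 1847 with a replicate block added. At 1 h alone they were 8 and 6, and at 2 h alone 198 and 101. Without single arrays, limma no longer called AT1G14550 (adjusted p up to 0.19 without JA pretreated 0 h replicate 1 or 2) and GID1B (adjusted p = 0.25 without JA pretreated 0 h replicate 1) after JA. LHCB4.2 (adjusted p up to 0.18 without JA pretreated 0 h replicate 1 or 2) lost it too. AT1G78410 (adjusted p up to 0.48 without GA pretreated 0 h replicate 1, 2 or 3, or GA pretreated flg22 1 h replicate 1 or 2, or GA pretreated flg22 2 h replicate 1 or 3) and AT5G14700 (adjusted p up to 0.39 without GA pretreated 0 h replicate 1, 2 or 3, or GA pretreated flg22 1 h replicate 1, or GA pretreated flg22 2 h replicate 1 or 2) lost the call after GA. MSRB5 (adjusted p up to 0.52 without GA pretreated 0 h replicate 2 or 3, or GA pretreated flg22 1 h replicate 1 or 2, or GA pretreated flg22 2 h replicate 1) and AT1G49450 (adjusted p up to 0.12 without GA pretreated 0 h replicate 2 or 3) lost it too. AT2G41090 (adjusted p up to 0.44 without GA+JA pretreated 0 h replicate 1, 2 or 3, or GA+JA pretreated flg22 1 h replicate 1 or 2, or GA+JA pretreated flg22 2 h replicate 1 or 2) and AT4G10270 (adjusted p = 0.051 without GA+JA pretreated 0 h replicate 1) lost the call after GA+JA. AT1G49450 (adjusted p up to 0.18 without GA+JA pretreated 0 h replicate 2 or 3, or GA+JA pretreated flg22 1 h replicate 1) lost it too.

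**Figure D3:**
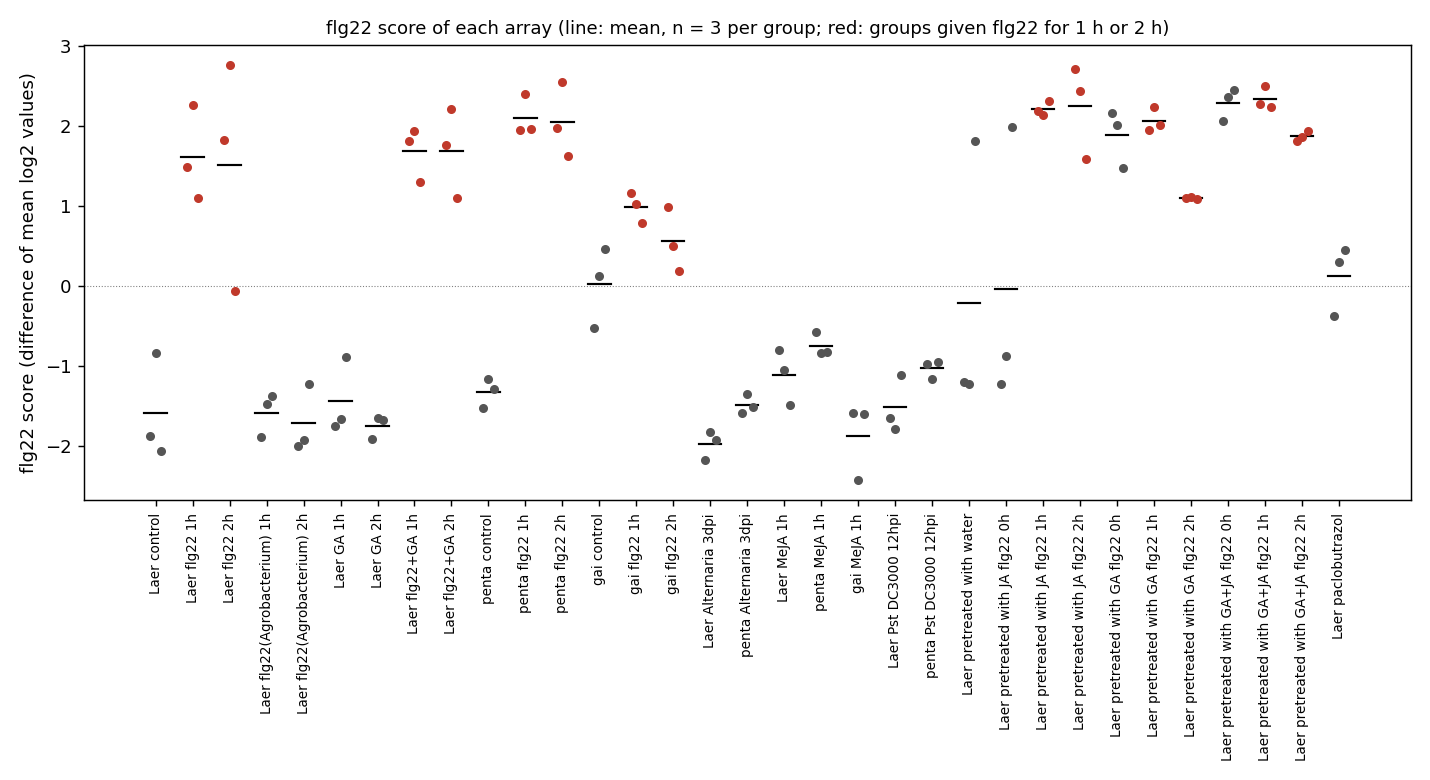
flg22 score of each array, the mean log2 value of 1516 probe sets raised at least 2-fold by flg22 in penta minus that of 1771 lowered as much, by group with the mean as a line, n = 3. Red groups had flg22 for 1 h or 2 h. GA pretreated arrays at 0 h averaged 1.89 and water arrays of the same array set -0.21.

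Compared within the pretreated arrays, the response after GA was lower than after JA for AT4G23030 (-4.91 ± 0.83), BGLU27 (AT3G60120, -4.84 ± 0.96) and CCR2 (AT1G80820, -4.52 ± 0.88) and CML42 (-4.15 ± 0.75), and higher for GID1A (2.11 ± 0.48). After GA+JA it was lower than after JA for AT4G23030 (-4.4 ± 0.83), DLAH (-4.05 ± 1) and CML42 (-3.66 ± 0.75). These differences were called for 1957 probe sets (901 up) and 1672 (752 up). As many came from 10 and 17 of 100 splits of the arrays. The GA count was 43, 271 or 5071 without JA pretreated 0 h replicate 1, 2 or 3, 1222 without JA pretreated flg22 2 h replicate 1 and 832 or 1088 without GA pretreated 0 h replicate 1 or 2. The GA+JA count was 9, 14 or 4682 without JA pretreated 0 h replicate 1, 2 or 3, 949 without JA pretreated flg22 2 h replicate 1 and 845 or 698 without GA+JA pretreated 0 h replicate 2 or 3. With their 18 arrays alone they were 2 and 1, and 1 and 2 with a replicate block added. Before flg22, CML42 stood above water by 2.57 ± 0.62 after GA and 2.48 ± 0.62 after GA+JA, GID1A stood below it after GA (-1.56 ± 0.39), and that state enters the difference. Single arrays carried the calls of BGLU27 (adjusted p = 0.056 without JA pretreated 0 h replicate 1) and CCR2 (adjusted p = 0.056 without JA pretreated 0 h replicate 1) after GA. GID1A (adjusted p = 0.094 without JA pretreated 0 h replicate 1) lost it too. AT4G23030 (adjusted p up to 0.052 without JA pretreated 0 h replicate 1 or 2) and DLAH (adjusted p up to 0.16 without JA pretreated 0 h replicate 1 or 2) lost the call after GA+JA. CML42 (adjusted p up to 0.068 without JA pretreated 0 h replicate 1 or 2) lost it too.

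Against the response without pretreatment, the response after JA was lower for UGT73B4 (-3.08 ± 0.49, adjusted p = 0.00065), UGT73B5 (-2.96 ± 0.59) and AT4G22530 (-2.61 ± 0.53), and the 43 glycosyltransferase genes differed downward as a group (adjusted p = 1e-05 preset, adjusted p = 0.019 with an estimated correlation). After JA itself, flg22 called neither UGT73B4 (-0.34 ± 0.35) nor UGT73B5 (0.66 ± 0.42). Before flg22, UGT73B4 stood at 10.46 ± 0.75 (SD) in JA pretreated arrays and at 4.23 ± 0.28 (SD) in control arrays of the other array set, so the difference may come from that level. After GA, the response was lower for AT2G23270 (-6.46 ± 1), AT1G14550 (-6.39 ± 1.4), DLAH (-6.36 ± 1) and CCR2 (-5.91 ± 0.88), a cinnamoyl-CoA reductase gene, and higher for AT4G20820 (3.82 ± 0.76) and GID1A (2.88 ± 0.48). After GA+JA it was lower for AT1G14550 (-6.24 ± 1.4) and CML37 (-4.69 ± 0.94). Before flg22, AT1G14550 already stood above water by 4.79 ± 1.1 after GA and 4.9 ± 1.1 after GA+JA. GID1A stood at -1.56 ± 0.39 after GA and CML37 at 2.48 ± 0.77 after GA+JA (adjusted p = 0.071 without water replicate 2), and that state enters the difference. Of 18 immunity components, 13 differed downward after GA (adjusted p = 3.5e-08 preset, adjusted p = 0.3 with an estimated correlation) and 13 after GA+JA (adjusted p = 8.4e-09 preset, adjusted p = 0.24 with an estimated correlation). JA gave 1 upward and 20 downward, GA 2770 and 2339, and GA+JA 2524 and 2181. The pretreated arrays had another value distribution than the unpretreated ones, so pretreatment and array set were confounded. The JA count was 10, 103 or 5 without Laer control replicate 1, 2 or 3, 178 without Laer flg22 2 h replicate 3 and 69 or 9 without JA pretreated 0 h replicate 1 or 2, and 0 with its 18 arrays alone (0 with a replicate block), and 1 at 1 h alone. At 1 h alone the GA count was 2704 and the GA+JA count 2790. Leaving out 1 array ended the call of UGT73B5 (adjusted p up to 0.13 without Laer control replicate 1 or 3, or JA pretreated 0 h replicate 3) and AT4G22530 (adjusted p up to 0.14 without Laer control replicate 1 or 3, or JA pretreated 0 h replicate 3).

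Paclobutrazol and water pretreatment were each compared with control across the 2 sets of arrays, where the median change over all probe sets was 0.59 in each. Against that shift, AT1G53540 (6.75 ± 1.1), Hop3 (5.11 ± 0.83) and UGT73B4 (4.59 ± 0.4) stood higher with paclobutrazol and PDF1.2 (-3.2 ± 0.74) and AT5G48490 (-4.66 ± 0.92) lower. With water, AT1G53540 (5.39 ± 1.1) and OSM34 (5.11 ± 0.76) stood higher and AT1G29660 (-4.89 ± 0.82) lower. Paclobutrazol was 15135 up and 1239 down and water 15178 up and 872 down as given. Water called 8647 with only its groups and a replicate block. After quantile normalization over all arrays they were 5048 up and 4450 down, and 4363 up and 4169 down. Within 1 array set, paclobutrazol against water gave higher AT5G55450 (3.51 ± 0.83), AT1G21520 (3.07 ± 0.58) and AT5G17760 (2.75 ± 0.42) and lower MSRB6 (AT4G04840, -3.18 ± 0.64) and AT1G63580 (-2.67 ± 0.33) and AT5G10040 (-2.43 ± 0.31). GID1B was not called (0.16 ± 0.32). This comparison called 823 higher and 449 lower, 654 or 2269 without water replicate 2 or 3 and 464 or 432 without paclobutrazol replicate 2 or 3. It called 0 by limma with its groups alone (0 with a replicate block), against 4261 at an unadjusted p under 0.05 on all arrays. Calls of named genes that ended when 1 array was left out were those of AT5G55450 (adjusted p = 0.1 without paclobutrazol replicate 1).

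Over the 40 comparisons, 880 tests of 22 gene lists were made and 116 passed with a preset correlation. With an estimated correlation 6 held: the GA genes after GA at 1 h and 2 h, after flg22 with GA, in control penta and in the Alternaria difference between penta and Laer, and the glycosyltransferase genes in flg22 after JA against no pretreatment. As many probe sets came from at least 8 of 100 splits of the arrays in adding GA to flg22, in the 4 differences of penta from Laer and in flg22 after JA against no pretreatment, and from 13 of 84 splits for flg22 in gai. Among the 27 splits that part as many numbered pairs, the real one included, as many came from 1 for flg22 in gai and from 2 for flg22 after GA, a share over 0.05. The 22 lists were built after the annotation and the structure of the samples had been seen.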

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

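The tests on the flg22 score and on the falls shared by Alternaria, Pst DC3000 and MeJA were chosen after those results were seen, while the counts over other splits of the arrays were planned, except in the 3 comparisons added later. The responses of penta and Laer differed, by limma's test of the difference, for 5 probe sets after flg22, 33 after Alternaria, 5 after Pst DC3000 and 18 after MeJA. GID1B differed after Alternaria (1.96 ± 0.45) and MeJA (2.3 ± 0.45), where it fell in Laer and was not called in penta. Control penta discs already had less of it than Laer (-1.81 ± 0.32), and that state enters these differences. The responses of gai and Laer differed for 1316 probe sets after flg22, CML37 among them (-4.63 ± 0.94), and for 2695 after MeJA, with CML37 at -6.15 ± 1.1. Its level in control gai discs (3.7 ± 0.77 above Laer) enters both. Against no pretreatment, the flg22 response differed for 21 probe sets after JA, 5109 after GA and 4705 after GA+JA. The difference in AT1G14550 was -6.39 ± 1.4 after GA and -6.24 ± 1.4 after GA+JA. Before flg22 it already stood above water by 4.79 ± 1.1 and 4.9 ± 1.1, and that state enters the difference. Against the response after JA, that after GA differed for 1957 probe sets and that after GA+JA for 1672, with CML42 at -4.15 ± 0.75 and -3.66 ± 0.75. CML42 stood above water by 2.57 ± 0.62 after GA and 2.48 ± 0.62 after GA+JA before flg22, which enters these differences too.

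Each comparison was recounted under other splits of its arrays, the real split included in the number, and the highest of the other splits is given in parentheses. Over all splits drawn, the share was under 0.05 in the following. It was not corrected over the comparisons, so it does not by itself exclude chance. The flg22 response in penta gave 8153, met in 1 of 84 splits (5160). The MeJA difference of gai gave 2695, met in 2 of 100 splits (2917) and the flg22 response after JA gave 5053, met in 4 of 84 splits (6316). The flg22 response gave 63 after GA, met in 2 of 84 splits (155) and 48 after GA+JA, met in 3 of 84 splits (87). The flg22 response against none gave 5109 after GA, met in 2 of 100 splits (5221) and 4705 after GA+JA, met in 1 of 100 splits (4482). The share was over 0.05 in the following. Adding GA to flg22 gave 5, met in 10 of 100 splits (362) and the flg22 response in gai gave 13, met in 13 of 84 splits (1379). The flg22 difference of penta gave 5, met in 27 of 100 splits (669) and the flg22 difference of gai gave 1316, met in 8 of 100 splits (3773). The Alternaria difference gave 33, met in 21 of 100 splits (1278) and the Pst DC3000 difference gave 5, met in 43 of 100 splits (630). The MeJA difference of penta gave 18, met in 15 of 100 splits (155) and the flg22 response after JA against none gave 21, met in 27 of 100 splits (10082). The flg22 response against that after JA gave 1957 after GA, met in 10 of 100 splits (3464) and 1672 after GA+JA, met in 17 of 100 splits (4755). With 3 arrays against 3 the 10 splits are too few for a share under 0.05. In Laer, flg22 at 1 h gave 6348 (647), flg22 at 2 h gave 7494 (4089) and flg22(Agrobacterium) at 1 h gave 0 (4). GA at 1 h gave 4 (26), flg22(Agrobacterium) at 2 h gave 0 (1), flg22 against flg22(Agrobacterium) at 1 h gave 6074 (33) and flg22 against flg22(Agrobacterium) at 2 h gave 8265 (2937). GA at 2 h gave 17 (155), control penta gave 263 (21), control gai gave 3415 (304) and Alternaria in Laer gave 4463 (70). Alternaria in penta gave 5151 (59), Pst DC3000 in Laer gave 4100 (657), Pst DC3000 in penta gave 5164 (146) and MeJA in Laer gave 5589 (39). MeJA in penta gave 7612 (16), MeJA in gai gave 8093 (1998), JA against water gave 37 (4237) and GA against water gave 3700 (4005). GA+JA against water gave 6283 (4122), paclobutrazol against control gave 16374 (2851), water against control gave 16050 (2108) and paclobutrazol against water gave 1272 (2788). Other splits with several times the real count, as in JA against water, point to a structure of the samples within the groups. In differences of 2 responses, splits may part treated from untreated arrays unevenly, so a share over 0.05 decides nothing there.

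Where replicate numbers paired the arrays, the real split was set against splits that part as many pairs, the real one included in the number. In Laer, flg22 at 1 h gave 6348, met in 1 of 4 (0). Adding GA to flg22 gave 5, met in 1 of 18 (0) and flg22(Agrobacterium) at 1 h gave 0, met in 4 of 4 (0). Control penta gave 263, met in 1 of 4 (1) and the flg22 response in gai gave 13, met in 1 of 27 (2). JA against water gave 37, met in 1 of 4 (1) and the flg22 response after GA gave 63, met in 2 of 27 (155). Held to these splits, the share was over 0.05 in the flg22 response after GA and under 0.05 in the flg22 response in gai, the reverse of that over all splits. Neither 4 nor 18 splits can give a share under 0.05. The splits that put same-numbered arrays together gave the higher counts in all of these comparisons but the flg22 response after GA.

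Control gai discs lay toward flg22-treated discs by a score, the mean of 1516 probe sets raised at least 2-fold by flg22 in penta minus that of 1771 lowered as much, which was -1.59 ± 0.66 (SD, n = 3) in Laer control, 0.02 ± 0.5 in gai control and 1.62 ± 0.59 in Laer after 1 h of flg22. That shift of gai control was 1.61 (SE 0.477), against 3.15 for flg22 in Laer. A line state unmoved by MeJA was argued against, since gai lay below Laer after it by -0.76 (SE 0.343). So was a single wrong label, since the lowest of 3 gai control arrays stood 0.31 above the highest Laer control array. The same flg22 exposure of all gai discs was argued against by the further rise of 0.76 (SE 0.325) in gai after flg22. A line state that MeJA lowers may remain. So may a response of gai discs to cutting or handling or a day or batch shared by the gai control arrays, untested.

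GA and GA+JA pretreated discs lay toward flg22-treated discs before any flg22, by a second score, the mean of 1518 probe sets raised at least 2-fold by flg22 against flg22(Agrobacterium) at 1 h in Laer minus that of 1215 lowered as much, which was 2.3 ± 0.33 and 2.72 ± 0.17 (SD, n = 3) against 0.58 ± 1.4 with water. With only their groups and a replicate block, the JA comparison with water, whose replicate numbers paired, called 641 probe sets, GA 0 and GA+JA 604. GA acting within 1 h to 2 h could not be told apart from longer exposure, since GA on discs moved this score by -0.07 (SE 0.464) and GA pretreatment by 1.72 (SE 0.847), a gap of 1.79 within 2 SE of 0.966. A swap of water replicate 3 with a GA pretreated array was argued against by a gap of 2.12 between the lowest GA pretreated array and the higher of the other water arrays, with an SD of 0.328 among GA pretreated arrays. Water replicate 3 itself stood 0.3 above the lowest GA pretreated array, so a factor other than GA could raise the score and cannot be told apart from GA, since 1 of 3 water arrays lay in that range.

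The same probe sets lay below control discs after Alternaria, Pst DC3000 and MeJA. Over 1080 probe sets lower by at least 2-fold after Alternaria in Laer, the medians in penta were -1.46 after Alternaria, -1.19 after Pst DC3000 and -1.17 after MeJA, the smallest being 79.6 percent of the largest. If the treated samples were intact plants, as in the protocol but against their labels, which say leaf discs, a constant difference from control discs may account for these falls and cannot be told apart from the treatments, because no intact mock group was analysed here while 41.3 percent were called lower after both other treatments, a share limited by the power of the calls. A transient of control discs that fades within 2 h was argued against, since the same probe sets stood at -0.0529 in flg22(Agrobacterium) discs at 2 h, 3.3 percent of the fall of -1.6 after Alternaria in Laer. That wounding or dissection raised them in all discs stays open.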

How the results depend on the processing

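Leaving out water replicate 3 and JA pretreated 0 h replicate 3 together was chosen after the results were seen, as were all settings of the 3 later comparisons. The fall of GID1B after GA at 2 h ranged from -2.54 to -2.23, the rise of CML37 after flg22 at 1 h from 4.99 to 6.72 and the rise of PORB after MeJA in Laer from 3.73 to 4 over their alternatives. Named genes kept direction and call in 1839 of 2099 alternative fits and lost the call in the same direction in 256. With 1 array left out, 2062 of 2235 kept it and 171 lost it. In none of these fits did a called gene reverse. Counts of probe sets moved by over 1.5 times as follows, and the cause was not tested except where stated.

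With a replicate block in the fit of all arrays, 38 of 40 counts stayed within 1.5 times, and the flg22 response in gai gave 23 and the flg22 response after JA against none gave 36. In the paired comparisons this block changed no other count by that much and no call among 154 list tests. With an estimated correlation 6 of 116 list tests held. With the lowest 30 percent of probe sets left out, over fewer probe sets tested, the flg22 difference of penta gave 2, the Alternaria difference gave 16, the Pst DC3000 difference gave 0, the MeJA difference of penta gave 10 and water against control gave 10692. With quantile normalization, JA against water gave 17, the flg22 response after GA gave 41, paclobutrazol against control gave 9498 and water against control gave 8532. With equal medians, the Pst DC3000 difference gave 3 and water against control gave 9379. Quantile normalization and equal medians remove by construction the shift between the 2 sets of arrays, which the comparisons of paclobutrazol and water with control carry.

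Array weights raised each count they moved. Control penta gave 761, flg22(Agrobacterium) at 2 h gave 1, GA at 1 h gave 167, GA at 2 h gave 1024 and adding GA to flg22 gave 8. Control gai gave 7222, the flg22 response in gai gave 2917, the flg22 difference of gai gave 6306, the Alternaria difference gave 100 and Pst DC3000 in Laer gave 7765. The Pst DC3000 difference gave 69, the MeJA difference of penta gave 60, the MeJA difference of gai gave 4965, JA against water gave 3394 and GA against water gave 9513. GA+JA against water gave 11383, the flg22 response after JA gave 15348, the flg22 response after GA gave 2782, the flg22 response after GA+JA gave 2221 and the flg22 response after JA against none gave 2277. Paclobutrazol against water gave 9095, the flg22 response after GA against none gave 8840, the flg22 response after GA+JA against none gave 8412, the flg22 response after GA against after JA gave 11481 and the flg22 response after GA+JA against after JA gave 10766.

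With only the groups of the comparison fitted, fewer arrays estimated the spread. GA at 1 h gave 2, flg22 at 2 h gave 1242, flg22 against flg22(Agrobacterium) at 2 h gave 2511 and GA at 2 h gave 0. Control penta gave 39, adding GA to flg22 gave 0, control gai gave 1831, the flg22 response in gai gave 29 and the flg22 difference of penta gave 0. Pst DC3000 in Laer gave 2626, the flg22 difference of gai gave 7, the Alternaria difference gave 1, MeJA in gai gave 4966 and the MeJA difference of gai gave 1298. GA against water gave 10, JA 0 and GA+JA 1349, and the flg22 response gave 3 after JA and 2459 after GA, their order reversed. Paclobutrazol against water gave 0. The flg22 response gave 646 after GA+JA, 0 after JA against none, 2 after GA against after JA and 1 after GA+JA against after JA.

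A replicate block was also added to the fits of only those groups. GA at 2 h gave 0, flg22 at 2 h gave 4286, flg22 against flg22(Agrobacterium) at 2 h gave 0 and GA at 1 h gave 0. Control penta gave 445, adding GA to flg22 gave 8, control gai gave 0, the flg22 response in gai gave 705 and the flg22 difference of penta gave 0. Alternaria in Laer gave 1228, the flg22 difference of gai gave 818, Alternaria in penta gave 2622, the Alternaria difference gave 0 and Pst DC3000 in Laer gave 371. Pst DC3000 in penta gave 2956, the Pst DC3000 difference gave 1, MeJA in gai gave 2716, the MeJA difference of gai gave 324 and JA against water gave 641. GA against water gave 0, GA+JA against water gave 604, the flg22 response after JA gave 410, the flg22 response after GA gave 4354 and the flg22 response after GA+JA gave 1847. Water against control gave 8647, the flg22 response after JA against none gave 0, paclobutrazol against water gave 0, the flg22 response after GA against after JA gave 1 and the flg22 response after GA+JA against after JA gave 2.

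At 1 h alone, counts moved in the following. The flg22 difference of penta gave 1, adding GA to flg22 gave 0, the flg22 difference of gai gave 452 and the flg22 response after JA gave 2907. The flg22 response after GA gave 8, the flg22 response after GA+JA gave 6, the flg22 response after JA against none gave 1, the flg22 response after GA against none gave 2704 and the flg22 response after GA+JA against none gave 2790. At 2 h alone, adding GA to flg22 gave 0, the flg22 response in gai gave 4, the flg22 difference of gai gave 652, the flg22 response after GA gave 198 and the flg22 response after GA+JA gave 101. With flg22(Agrobacterium) at 2 h as baseline GA at 2 h gave 6, while the count at 1 h stayed within 1.5 times. With both arrays that stand apart left out, JA against water gave 24, GA against water gave 6463, the flg22 response after JA gave 8357, paclobutrazol against water gave 2647, the flg22 response after GA against after JA gave 5401 and the flg22 response after GA+JA against after JA gave 5003.

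Each array was left out in turn, and the lowest and highest counts are given. In Laer, flg22 at 1 h gave 3915 to 6038, flg22 at 2 h gave 3430 to 8698, flg22(Agrobacterium) at 1 h gave 0 to 2 and flg22(Agrobacterium) at 2 h gave 0 to 1. GA at 1 h gave 3 to 6, flg22 against flg22(Agrobacterium) at 1 h gave 3887 to 5779, flg22 against flg22(Agrobacterium) at 2 h gave 4168 to 9382 and GA at 2 h gave 8 to 21. Control penta gave 87 to 325, adding GA to flg22 gave 3 to 9, control gai gave 1669 to 3554 and the flg22 response in penta gave 6213 to 8532. The flg22 response in gai gave 1 to 31, the flg22 difference of penta gave 2 to 12, the flg22 difference of gai gave 251 to 2958 and Alternaria in Laer gave 3498 to 3937. Alternaria in penta gave 3862 to 4705, the Alternaria difference gave 23 to 46, Pst DC3000 in Laer gave 2990 to 4037 and Pst DC3000 in penta gave 3938 to 4680. MeJA in Laer gave 4562 to 4777, the Pst DC3000 difference gave 3 to 10, MeJA in penta gave 6268 to 7007 and MeJA in gai gave 6650 to 7491. JA against water gave 6 to 143, the MeJA difference of penta gave 10 to 25, the MeJA difference of gai gave 1352 to 3171 and GA against water gave 522 to 6293. GA+JA against water gave 3557 to 7838, the flg22 response after JA gave 945 to 8248, the flg22 response after GA gave 7 to 87 and the flg22 response after GA+JA gave 19 to 84. Paclobutrazol against control gave 15070 to 15932, the flg22 response after JA against none gave 5 to 178, the flg22 response after GA against none gave 3767 to 6194 and the flg22 response after GA+JA against none gave 3420 to 5902. Water against control gave 14906 to 15411, paclobutrazol against water gave 432 to 2269, the flg22 response after GA against after JA gave 43 to 5071 and the flg22 response after GA+JA against after JA gave 9 to 4682. Leaving out 1 array leaves 2 in its group, and limma takes the spread from all groups. Dim probe sets limit detection on arrays, and no background level is given in the sources used here.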

Other observations

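Transcripts of AT5G10040 fell after flg22 in gai (-1.51 ± 0.26) and lay lower with paclobutrazol than with water (-2.43 ± 0.31). AT5G66985 fell after flg22 in gai (-1.33 ± 0.19), and AT4G10270 after flg22 in GA+JA pretreated discs (-1.67 ± 0.25). These genes were set side by side after their values were seen, and the changes were not compared with each other by a test.

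flg22 scores of single arrays, in log2 units and from the probe sets changed at least 2-fold by flg22 in penta, differed within groups. The water arrays stood at -1.2, -1.23 and 1.81, and JA pretreated 0 h replicate 3 at 1.99. By root mean square deviation from the group mean, water replicate 3 (0.569), JA pretreated 0 h replicate 3 (0.568), gai MeJA replicate 2 (0.505) and Laer flg22 2 h replicate 3 (0.439) lay furthest out.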
